A study of Escherichia coli with 8 samples.

How the data were processed

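The data were RNA-seq expression values from Escherichia coli W grown in a glycerol-containing minimal medium with some yeast extract: 8 libraries in 4 groups of 2, wild type and the narQXLP deletion strain, each with an empty vector or a NarQ overexpression plasmid. The authors deposited FPKM per locus and library, and these values were used as they stand. Per the submitters' processing notes, TopHat2 2.0.13 and Cuffdiff 2.2.0 were used; which step each carried out, and the genome build, are not given in the sources used here. FPKM keep no read counts, so depth is unknown, count models could not be used, and the precision of low values could not be judged. The raw reads and 2 unnamed columns holding 4 free-text notes were not used here.

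The table held 4860 loci. A symbol came from the gene column for 2699 and from the product name for 201, and 1960 had none; 89 symbols were carried by more than 1 locus and are printed with a locus tag. A table of K-12 genes gave symbols and lengths (2533 loci had a matching length) and no coordinates. In all 189 loci were listed at 0 in the 8 libraries. A value of exactly 0 may be a failed estimate, so no fold change is printed against a group at 0 throughout, and values of short loci are uncertain.

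Loci with at least 1 FPKM in at least 2 libraries were kept, which left 4651. limma 3.58.1 in R 4.3.3 fitted log2(FPKM + 1) with 1 mean per group over the 8 libraries, with empirical Bayes moderation and a trend of variance on mean level (residual degrees of freedom 4, prior 2.6). A pseudocount of 1 understates fold changes of low genes. There were 5 comparisons: NarQ against empty vector in wild type, the same in the deletion strain, the difference of these effects (interaction), and deletion against wild type with empty vector and with NarQ. A locus was called at a Benjamini-Hochberg adjusted p under 0.05, with a second count at an absolute log2 fold change of at least 1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The model, thresholds, 32 gene lists, naming rule and alternatives were chosen before the data were examined, except where said otherwise.

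The gene lists were written from general knowledge of E. coli regulation and tested with camera in limma at a preset inter-gene correlation of 0.01, for lists with at least 3 measured members. camera with an estimated correlation and fry were the alternatives. The estimated correlation was far above the preset for some lists, such as 0.752 for ribosomal proteins and 0.393 for ATP synthase. For such lists the p-values at the preset may be much too small. It was near the preset for others, such as 0.019 for flagella and chemotaxis. Counts adjusted over the list alone used the p-values of the members only. Named genes were, for each comparison, the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 10 FPKM in a group compared and both libraries of one group above both of the other; for the interaction, a mean of at least 10 FPKM in any group and no condition on overlap. narQ, narX, narL and narP were always named, and for each list discussed up to 4 called members with the smallest p, or the 2 smallest where none was called. A gene singled out in any other way was chosen after its values were seen.

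The alternatives were pseudocounts of 0.1 and 10, no filter and a filter of 10 FPKM, median-ratio scaling, quantile normalization, moderation without trend, replicate number as a block, only the libraries of the groups compared, and each library left out in turn. A list alternative without symbols carried by more than 1 locus was added after the data were seen. With a library left out its partner stands alone, and its spread is taken from the other groups. In a simulation with 200 changed loci, changes of 1 and 2 on the log2 scale were recovered in 64 and 92% of cases for NarQ in wild type, 55 and 91% for NarQ in the deletion strain, 23 and 81% for the interaction, 58 and 88% for the strains with empty vector and 57 and 93% for the strains with NarQ, with 5, 6, 4, 7 and 13 false calls. The simulated noise was normal, with the moderated spread of each locus, equal in all groups and without scaling differences. Only loci with a mean level of at least 10 FPKM were changed. Recovery may therefore be lower, and false calls more frequent, in the real data.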

Results

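Transcript levels were measured by RNA-seq in Escherichia coli W, a fast-growing laboratory and production strain, in order to look for genes under the control of NarQ with a part in taking up 3-hydroxypropionate (3-HP), a small organic acid of industrial interest. NarQ and NarX are membrane sensor kinases for nitrate and nitrite, and NarL and NarP are the response regulators they act on. Wild type and a strain deleted for narQ, narX, narL and narP each carried an empty vector or a plasmid overexpressing NarQ, which gave 4 groups of 2 libraries. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values were FPKM for 4860 loci, of which 4651 were tested. FPKM keep no record of the reads behind them, so the depth of the 8 libraries is unknown. The FPKM of a library summed to between 6246649 and 10296879, its 10 highest loci held 60.7 to 67.3% of that sum, and its median locus stood at 68.6 to 79.9 FPKM. Between 242 and 356 loci per library were listed at 0, the highest count in the second NarQ library of the deletion strain. Correlations across genes of log2(FPKM + 1) within a group were 0.968 for wild type with empty vector, 0.949 for wild type with NarQ, 0.942 for the deletion with empty vector and 0.923 for the deletion with NarQ. The first empty-vector and the first NarQ library of the deletion strain correlated at 0.950, above both libraries' correlation with their own partner. Some wild-type libraries were also nearer to them than that partner. The first deletion NarQ library correlated with each wild-type library at 0.925 to 0.931. The first deletion empty-vector library correlated with the wild-type empty-vector libraries at 0.9485 and 0.9434, against 0.9422 with its partner. The 3 structural RNA genes that could be tested were not called as a list in any of the 5 comparisons (camera, adjusted p between 0.82 and 0.946). This test compares group means of few loci, so it cannot judge the quality of single libraries. Loci for 5S ribosomal RNA (rrf) held 7.997% of the FPKM in the first deletion empty-vector library and 2.656% in the second. These were the lowest share of the 8 libraries and the highest but that of the second deletion NarQ library (8.767%). Whether RNA quality differed between libraries was not tested.

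The 4 regulator genes were read first, as a check of the labels. narQ stood at 27.9 ± 2.72 FPKM (SD, n = 2 in this and every group) in wild type with empty vector and rose to 1880 ± 106 with the plasmid, 65.1-fold on the log2(FPKM + 1) scale (log2 fold change 6.02 ± 0.14 SE, limma adjusted p = 8.98e-06). In the deletion strain it rose from 6.48 ± 0.808 to 1697 ± 61.7, 228-fold (7.83 ± 0.14, adjusted p = 1.6e-06). The plasmid levels of both strains differed by a log2 fold change of -0.15 (adjusted p = 0.466; 0.12 after quantile normalization). narX was 65.7 and 60.1 FPKM in wild type with empty vector and 57.1 and 57.9 with NarQ, and was listed at 0 in all 4 deletion libraries. narP was 78.7 and 90.1, then 71.3 and 76.6 in wild type, against 0.962 and 0.998 with empty vector and 0 and 1.88 with NarQ in the deletion. narL did not reach 0: it was 116 ± 6.54 and 73.2 ± 2.23 FPKM in wild type without and with NarQ, and 16.5 ± 4.96 and 12.2 ± 1.95 in the deletion, where it was lower both with empty vector (log2 fold change -2.76, adjusted p = 0.00593) and with NarQ (-2.50, adjusted p = 0.00165). Whether part of narL or narQ, at 6.48 FPKM with empty vector, remained in the deletion strain could not be read from these values. The calls of narP and narL with empty vector were lost without either wild-type empty-vector library or the second deletion empty-vector library, and that of narQ (-1.95, adjusted p = 0.0047) without the latter.

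**Figure D1:**
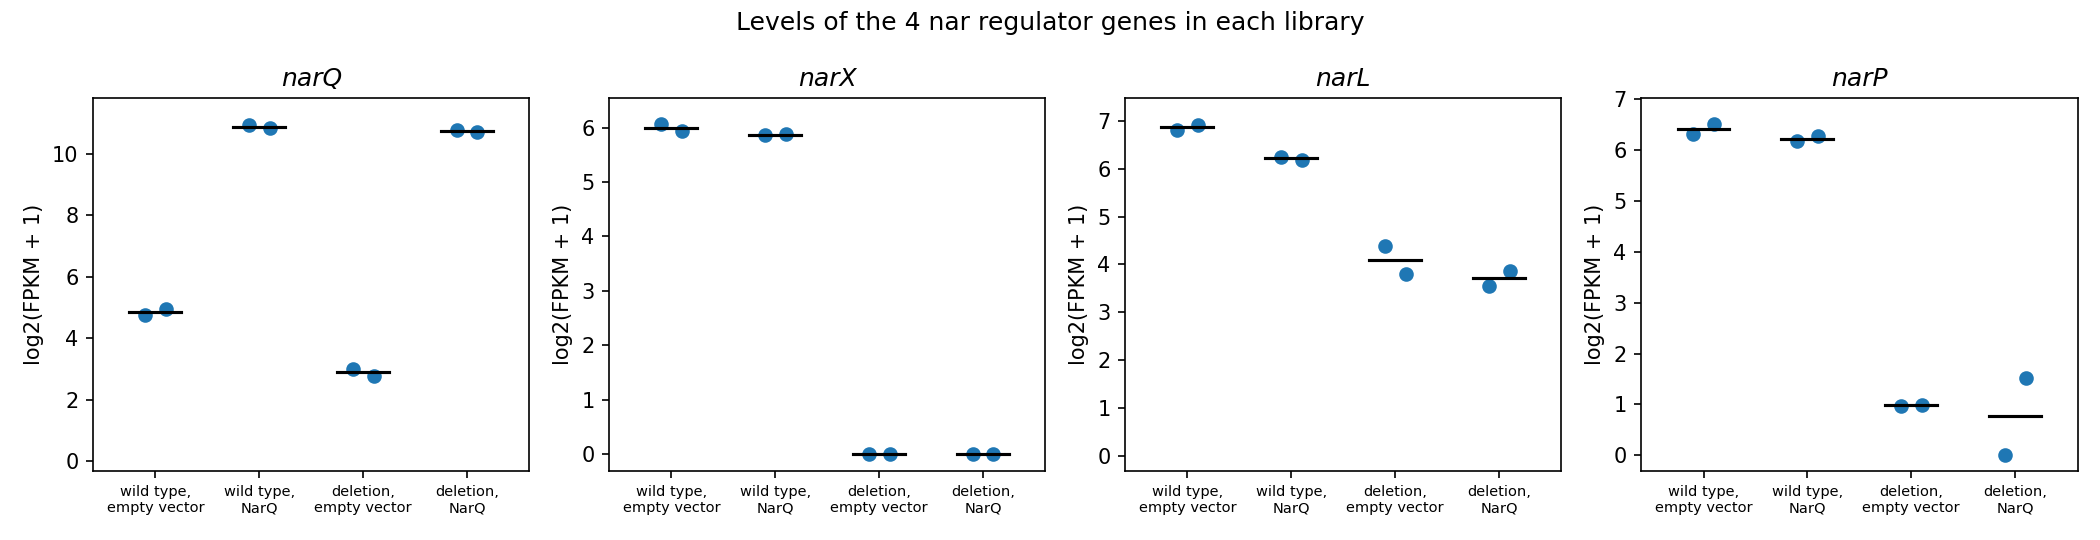
Levels of narQ, narX, narL and narP, as log2(FPKM + 1), in the 4 groups; each point is 1 library and each line the mean of a group's 2 libraries. narX was listed at 0 in the 4 deletion libraries, while narL stood at 16.5 FPKM there with empty vector and at 12.2 with NarQ.

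The first comparison asked which transcripts differed when wild type overexpressed NarQ. Genes for the biofilm polysaccharide poly-N-acetylglucosamine rose: pgaA, the export porin, went from 10.7 ± 0.422 to 117 ± 0.676 FPKM (log2 fold change 3.34 ± 0.15, adjusted p = 0.000503), and pgaB, pgaC and pgaD rose by 3.29, 3.13 and 2.49. Genes for swimming fell. Of 77 measured flagellar and chemotaxis loci 44 fell, 0 rose and 33 were not called, and 51 fell and 1 rose when adjusted over the list alone. flgE, the hook protein, fell from 558 ± 11.8 to 21.1 ± 10.8 FPKM (-4.75 ± 0.39, adjusted p = 0.00146), the rod and basal-body genes flgC (ECW_RS06070), flgB (ECW_RS06065) and flgF (ECW_RS06085) changed by -6.26, -5.51 and -5.17, and cheY, the chemotaxis response regulator, by -2.04. fliM and fliN of the motor switch changed by -3.24 and -4.16. The list was called by camera (adjusted p = 1.11e-14), and not with an estimated correlation (adjusted p = 0.0725 with an estimated correlation). It holds 25 loci of a second flagellar gene set, 1 of which fell, beside 52 other loci, 43 of which fell. In all, 771 of 4651 loci were called, 233 higher and 538 lower, 337 of them with an absolute log2 fold change of at least 1. The higher share was 30.2%, and 38.1% after median-ratio scaling or 44.2% after quantile normalization. The count was 164 and 114 without the first and the second empty-vector library and 384 and 284 without the first and the second NarQ library of wild type, and the flagellar count was 29 and 28 without the 2 empty-vector libraries. Of 63 named genes called, 34 kept their call with each of the 8 libraries left out in turn, among them pgaA, pgaB, pgaC, flgE and fliN.

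Genes of nitrate and nitrite respiration moved in both directions. narH (ECW_RS06770) and narI (ECW_RS06780), subunits of the membrane-bound nitrate reductase, rose by 1.84 (23.9 ± 5.09 to 87.8 ± 18.1 FPKM, adjusted p = 0.0061) and 1.94, and fdnG (ECW_RS08210), the catalytic subunit of formate dehydrogenase-N, by 2.10. napA, of the periplasmic nitrate reductase, fell from 88.9 ± 17.1 to 7.85 ± 1.39 FPKM (-3.34 ± 0.25, adjusted p = 0.00121) and napC changed by -1.51. Of 29 measured nitrate-induced genes 4 rose, 6 fell and 19 were not called, 4 rose and 8 fell adjusted over the list alone, and the list was not called (camera adjusted p = 0.665; adjusted p = 0.803 with an estimated correlation). Of 21 nitrate-repressed genes 5 fell, 0 rose and 16 were not called, and 6 fell adjusted over the list alone. Among them were the fumarate reductase subunits frdD (-2.61) and frdA (162 ± 27.7 to 31.0 ± 1.95 FPKM, -2.34, adjusted p = 0.000997), alcohol dehydrogenase adhE (-1.63) and pyruvate formate-lyase pflB (-1.36), while the list missed the threshold (camera adjusted p = 0.0501; adjusted p = 0.332 with an estimated correlation). Without the first empty-vector library 1 nitrate-induced gene rose and 2 fell, and narH and narI were no longer called. Without the second, 1 rose and 1 fell, and fdnG, narI and napC were not called, and without the second NarQ library 2 rose and 3 fell and narI was not called.

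Maltose, glycerol, amino acid biosynthesis, nitrogen-limitation and general stress genes fell more often than they rose. All 11 measured maltose genes were lower and 9 fell (10 adjusted over the list alone; 0 rose), among them malE, the maltose-binding protein (754 ± 90.4 to 259 ± 24.5 FPKM, -1.54, adjusted p = 0.00307), malK (-1.47) and lamB (-1.28). For maltose genes camera gave adjusted p = 3.38e-07, and adjusted p = 0.21 with an estimated correlation. Of 15 glycerol genes 10 fell, 2 rose and 3 were not called, the same numbers adjusted over the list alone: glycerol kinase glpK went from 4414 ± 177 to 1898 ± 220 FPKM (-1.22, adjusted p = 0.00391) and glpA changed by -1.01, while glpQ and glpT, for uptake and use of glycerophosphodiesters and glycerol-3-phosphate, rose by 1.05 and 0.62. For glycerol genes camera gave adjusted p = 0.00358, and adjusted p = 0.228 with an estimated correlation. Amino acid biosynthesis genes fell in 28 of 43 cases and rose in 0 (31 fell adjusted over the list alone), including tryptophan synthase trpB (-2.20) and trpA (-2.25), ilvD (-1.87) and hisH (-1.31). For amino acid biosynthesis camera gave adjusted p = 6.31e-12, and adjusted p = 0.138 with an estimated correlation. Nitrogen-limitation genes fell in 14 of 23 cases and rose in 0 (16 fell adjusted over the list alone), with the regulator glnG at -1.44, glnP at -0.94 and the arginine catabolism gene astD at -1.67. For nitrogen-limitation genes camera gave adjusted p = 2.32e-07, and adjusted p = 0.21 with an estimated correlation. General stress genes under the sigma factor RpoS fell in 13 of 18 cases and rose in 0 (15 fell adjusted over the list alone), with catalase katE at -1.44 and yeaG at -1.49. For general stress genes camera gave adjusted p = 8.96e-08, and adjusted p = 0.21 with an estimated correlation. Without the first and the second empty-vector library the falling members numbered 5 and 3 of maltose, 3 and 1 of glycerol, 14 and 10 of amino acid biosynthesis, 1 and 2 of nitrogen limitation and 5 and 2 of general stress. Without the first and the second NarQ library 5 and 5 glycerol and 7 and 9 nitrogen-limitation genes fell, and without the second 5 maltose and 7 general stress genes. The calls of lamB, glpA and glpQ ended without the second empty-vector library, and those of glpQ, glnP and astD without the first, astD also without the second.

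Ribosomal protein and sulfate assimilation genes were higher. Of 55 ribosomal protein loci 16 rose, 0 fell and 39 were not called, and 30 rose adjusted over the list alone. For ribosomal protein genes camera gave adjusted p = 1.11e-14, and adjusted p = 0.363 with an estimated correlation. rpsO rose from 6889 ± 152 to 20140 ± 4090 FPKM (1.53, adjusted p = 0.00676), rpsT by 1.36 and rpsC by 0.87. Of 21 sulfate assimilation genes 7 rose, 0 fell and 14 were not called, and 8 rose adjusted over the list alone, among them sulfite reductase cysI (1.42) and cysJ (1.18) and the sulfate transporter genes cysW (1.46) and cysA (1.04). For sulfate assimilation genes camera gave adjusted p = 5.77e-06, and adjusted p = 0.21 with an estimated correlation. The ribosomal count was 0 without either empty-vector library, 1 and 8 without the first and the second NarQ library, 6 after quantile normalization and 8 when limma's variance prior had no trend, while rpsT lost its call without any of these 4 libraries rpsO without either empty-vector library and rpsC without these or the first NarQ library. The sulfate count was 4 and 1 without the first and the second empty-vector library and 4 without the first NarQ library, and cysW, cysA and cysJ were not called without the second empty-vector library.

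Among genes closest to the question of 3-HP import, 2 of 21 measured carboxylate transporters fell and 0 rose: acetate permease actP (70.2 ± 9.43 to 31.9 ± 1.75 FPKM, -1.11, adjusted p = 0.0167) and lactate permease lldP (-0.63, adjusted p = 0.0332). The same 2 were counted when adjusted over the list alone, 19 transporters were not called, and neither was the list (camera adjusted p = 0.742; adjusted p = 0.813 with an estimated correlation). Of 10 genes of propionate and 3-HP metabolism 3 fell and 7 were not called, and 4 fell adjusted over the list alone: ydfG, which encodes a 3-hydroxy acid dehydrogenase (-0.81, adjusted p = 0.00955), the propionate regulator prpR (-0.75) and acetyl-CoA synthetase acs (-0.68). That list was not called either (camera adjusted p = 0.252; adjusted p = 0.372 with an estimated correlation). The transporter count was 0 by limma without any one of the 4 wild-type libraries, and the propionate count was 0 and 1 without the first and the second empty-vector library and 0 without the second NarQ library. prpR lost its call without any one of the 4 wild-type libraries, acs without either empty-vector or the second NarQ library, and ydfG without the first empty-vector or the second NarQ library. Of the 32 lists 18 were called, 3 up and 15 down, and 0 with an estimated correlation, where the smallest adjusted p was 0.0725.

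**Figure D2:**
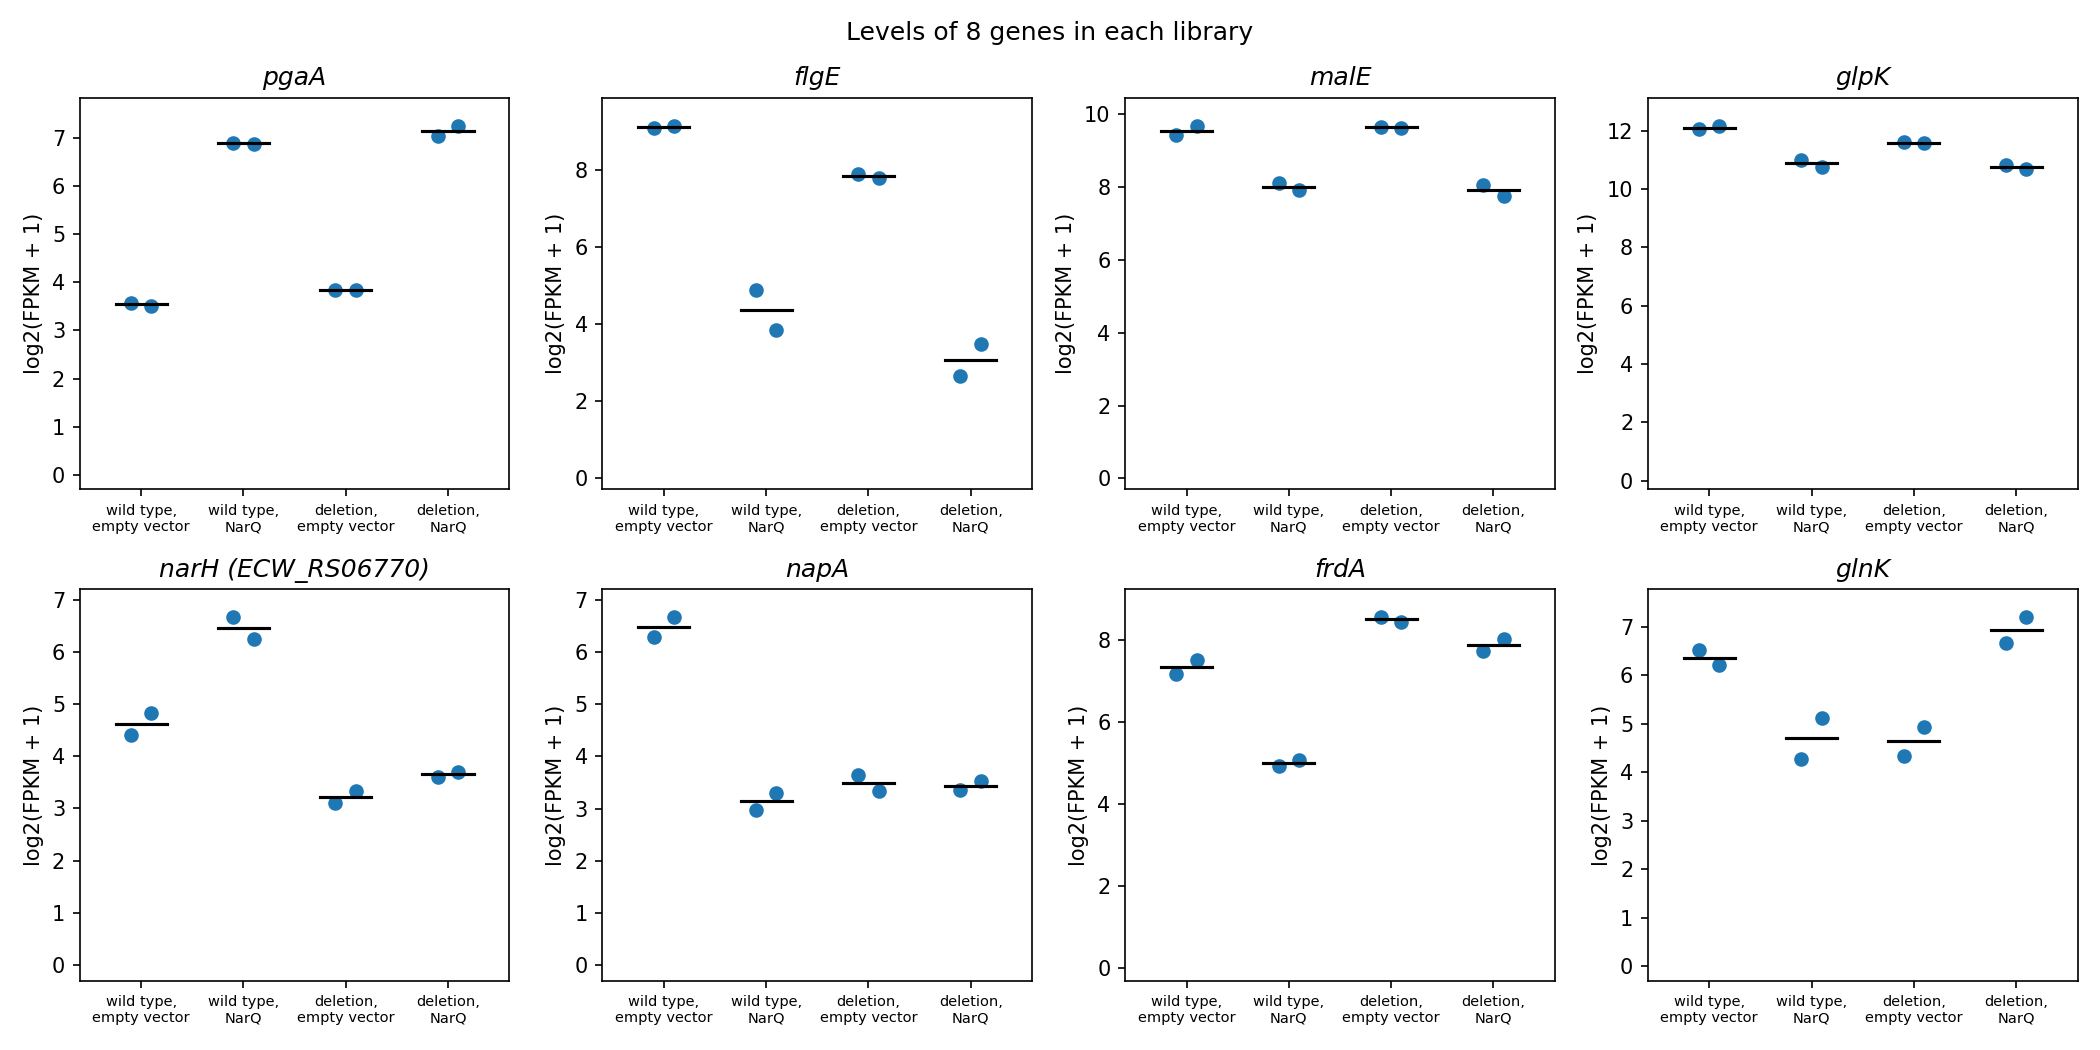
Levels of 8 genes, as log2(FPKM + 1), in the 4 groups; each point is 1 library and each line the mean of a group's 2 libraries. With NarQ, pgaA rose from 10.7 to 117 FPKM in wild type and from 13.3 to 141 in the deletion strain, and flgE fell from 558 to 21.1 and from 232 to 7.68.

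The second comparison asked the same of the strain labelled as deleted for narQ, narX, narL and narP. The pga genes rose here as well, pgaA from 13.3 ± 0.1 to 141 ± 14.6 FPKM (3.30 ± 0.15, adjusted p = 0.000511), with pgaB, pgaC and pgaD at 2.95, 2.47 and 1.88. uhpT, the hexose phosphate transporter, rose from 5.62 ± 1.61 to 101 ± 10.8 FPKM (3.96 ± 0.32, adjusted p = 0.00199), and the small protein gene sgrT, which lies within the small RNA SgrS, by 2.48. Flagellar genes fell in 43 of 77 cases, 0 rose and 34 were not called, and 49 fell and 2 rose adjusted over the list alone. flgE fell from 232 ± 11.8 to 7.68 ± 3.42 FPKM (-4.80 ± 0.39, adjusted p = 0.00199), the flagellar sigma factor gene fliA from 253 ± 43.7 to 10.6 ± 3.07 (-4.46, adjusted p = 0.000511) and flagellin fliC from 361 ± 40.2 to 60.5 ± 4.86 (-2.55). flgB (ECW_RS06065) was 437 and 440 FPKM with empty vector and 1.04 and 0 with NarQ, and fliO 131 and 143 against 4.92 and 0. This list was called by camera (adjusted p = 1.18e-28) and kept its call with an estimated correlation (adjusted p = 0.0194 with an estimated correlation). In all 189 loci were called, 76 higher and 113 lower, 129 of them with an absolute log2 fold change of at least 1. The count was 86 and 84 without the first and the second wild-type empty-vector library, 62 and 41 without the first and the second deletion empty-vector library, 69 without the second deletion NarQ library and 20 with the deletion libraries alone, and the flagellar count was 22 without either deletion empty-vector library and 11 with the deletion libraries alone. Of 40 named genes called, 15 kept their call with each library left out in turn, among them uhpT, pgaA, pgaB, pgaC, flgE, fliA and fliC, and 11 kept it with the deletion libraries alone. The call of sgrT was lost without either deletion empty-vector or either deletion NarQ library, that of pgaD without these or either wild-type empty-vector library, and that of fliO without either deletion empty-vector library.

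Maltose and glycerol genes fell in the deletion strain too. Of 11 maltose genes 7 fell, 0 rose and 4 were not called, and 10 fell adjusted over the list alone, with malE at 801 ± 14.7 and 242 ± 36.3 FPKM (-1.73, adjusted p = 0.0024), lamB at -2.03 and malK at -1.67. For maltose genes camera gave adjusted p = 1.25e-10, and adjusted p = 0.156 with an estimated correlation. Of 15 glycerol genes 8 fell, 0 rose and 7 were not called, and 10 fell and 1 rose adjusted over the list alone, with glpB at -1.69, glpC at -1.43 and glpK at 3066 ± 41 and 1717 ± 112 FPKM (-0.84, adjusted p = 0.0224). For glycerol genes camera gave adjusted p = 8.01e-07, and adjusted p = 0.156 with an estimated correlation. ATP synthase genes fell in 3 of 9 cases and rose in 0 (7 fell adjusted over the list alone), among them atpC (-1.03). For ATP synthase genes camera gave adjusted p = 1.77e-05, and adjusted p = 0.267 with an estimated correlation. Nitrogen-limitation genes rose in 5 of 23 cases and fell in 0 (9 rose adjusted over the list alone): glnK, a PII signalling protein, by 2.30 (24.4 ± 7.55 to 124 ± 31.9 FPKM, adjusted p = 0.022), nac by 1.56, amtB, the ammonium channel, by 1.52, astC by 1.03 and glutamine synthetase glnA by 0.95. For nitrogen-limitation genes camera gave adjusted p = 3.07e-05, and adjusted p = 0.333 with an estimated correlation. Without the first and the second deletion empty-vector library the counts were 4 and 3 for maltose, 1 and 0 for glycerol, 0 and 0 for ATP synthase and 1 and 0 for nitrogen limitation, and without the second deletion NarQ library 0 glycerol, 0 ATP synthase and 1 nitrogen-limitation genes were called. Without either wild-type empty-vector library 3 glycerol, 0 ATP synthase and 2 nitrogen-limitation genes were called, and without either wild-type NarQ library 5, 1 and 3. The fit without the first deletion NarQ library gave 1 ATP synthase and 3 nitrogen-limitation genes, and with the deletion libraries alone 1 maltose gene and 0 of the other 3 lists.

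Nitrate-responsive genes gave few calls in the deletion strain. Of 29 nitrate-induced genes 1 rose, 0 fell and 28 were not called, likewise adjusted over the list alone: nrfA, the periplasmic nitrite reductase, rose from 10.8 ± 0.908 to 27.4 ± 4.26 FPKM (1.27, adjusted p = 0.0294), and the list was not called (camera adjusted p = 0.842; adjusted p = 0.93 with an estimated correlation). Of 21 nitrate-repressed genes 0 were called by limma and 5 fell adjusted over the list alone. There dmsB (ECW_RS05125) and focA stood at -1.12 (adjusted p = 0.0801) and -0.55 (adjusted p = 0.0841), and the list was called lower. For nitrate-repressed genes camera gave adjusted p = 0.00543, and adjusted p = 0.217 with an estimated correlation. Ribosomal protein genes had 0 calls by limma among 55, also adjusted over the list alone, with rplN at -0.54 (adjusted p = 0.151), while the list was called lower with a median of -0.27. For ribosomal protein genes camera gave adjusted p = 1.03e-06, and adjusted p = 0.778 with an estimated correlation. Of 21 carboxylate transporters 2 fell, 1 rose and 18 were not called, and 7 fell and 2 rose adjusted over the list alone: dcuA, a C4-dicarboxylate carrier, changed by -0.86 (adjusted p = 0.0172), the galactarate transporter garP by -1.39 (adjusted p = 0.0175) and the alpha-ketoglutarate permease kgtP by 1.22 (adjusted p = 0.0234; camera for the list 0.0213, adjusted p = 0.254 with an estimated correlation). In the propionate and 3-HP list 0 of 10 were called by limma, also adjusted over the list alone; prpR stood at 0.38 (adjusted p = 0.253) and scpB at 1.03 (adjusted p = 0.259), and camera gave adjusted p = 0.487 (adjusted p = 0.772 with an estimated correlation). nrfA was called only with all 8 libraries or without the first deletion NarQ library. dcuA, garP and kgtP were not called without either deletion empty-vector library or the second deletion NarQ library, kgtP also not without either wild-type empty-vector library and garP also not without the second. Of the 32 lists 12 were called, 1 up and 11 down, and 1, the flagellar list, with an estimated correlation.

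Whether the effect of NarQ differed between the strains was tested as an interaction, the log2 fold change in the deletion strain minus that in wild type. Nitrogen-limitation genes had the highest median difference of the 9 called lists, 1.48: glnK was 81.7 ± 12.3 and 26.1 ± 11 FPKM without and with NarQ in wild type and 24.4 ± 7.55 and 124 ± 31.9 in the deletion strain (difference 3.96 ± 0.51, adjusted p = 0.0261), with nac at 2.83, amtB at 2.71 and glnG at 2.03. Of 23 such genes 14 had a higher and 0 a lower effect in the deletion strain, 18 higher adjusted over the list alone. For nitrogen-limitation genes camera gave adjusted p = 1.72e-10, and adjusted p = 0.399 with an estimated correlation. Amino acid biosynthesis genes had a higher effect in 14 of 43 cases and a lower one in 1, 31 and 5 adjusted over the list alone, among them lysA (3.33), trpB (2.69) and trpA (2.57). For amino acid biosynthesis camera gave adjusted p = 4.13e-07, and adjusted p = 0.399 with an estimated correlation. General stress genes had a higher effect in 8 of 18 cases and a lower one in 0, 12 higher adjusted over the list alone, with katE at 1.42 and otsB at 1.36. For general stress genes camera gave adjusted p = 8.75e-07, and adjusted p = 0.402 with an estimated correlation. napA, at 88.9 and 7.85 FPKM in wild type and 10.3 and 9.86 in the deletion strain, differed by 3.29 ± 0.36, napB by 3.54 and uhpT by 3.46. napD was also called (adjusted p = 0.0398), at 21.9 and 53.1 FPKM without and 1.52 and 5.36 with NarQ in wild type, against 0 and 0, then 1.62 and 1.74 in the deletion strain. Ribosomal protein genes had a lower effect in 3 of 55 cases and a higher one in 0, 37 lower adjusted over the list alone, with rpsO at -1.94, rpsT at -1.81 and rplV at -1.53. For ribosomal protein genes camera gave adjusted p = 2.12e-22, and adjusted p = 0.446 with an estimated correlation. In the sulfate list cysW (-1.42) and cysI (-1.19) were the 2 of 21 with a lower effect and 0 had a higher one, while 8 were lower and 1 higher adjusted over the list alone. For sulfate assimilation genes camera gave adjusted p = 4.84e-05, and adjusted p = 0.399 with an estimated correlation. fdnG (ECW_RS08210) differed by -2.24 and glpQ by -1.84. Nitrate-induced genes had 4 higher and 1 lower effect among 29, 9 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.455; adjusted p = 0.584 with an estimated correlation). In the flagellar list 0 of 77 were called by limma, also adjusted over the list alone, where fliO (-3.42, adjusted p = 0.118) and flgB (ECW_RS06065; -2.76, adjusted p = 0.127) had the smallest p, and the list was not called (camera adjusted p = 0.137; adjusted p = 0.446 with an estimated correlation). In all 217 loci were called, 174 with a higher and 43 with a lower effect in the deletion strain, 182 at an absolute difference of at least 1, and 9 lists were called, 0 with an estimated correlation.

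These interaction calls depended on single libraries. limma called 0 loci without either wild-type empty-vector library, the second wild-type NarQ library, the second deletion empty-vector library or the second deletion NarQ library, where 736, 750, 942, 908 and 978 loci had an unadjusted p under 0.05, and each list above then had 0 called members. It called 52 without the first wild-type NarQ library, 9 without the first deletion empty-vector library and 229 without the first deletion NarQ library, and 0 of the 31 named genes called kept their call with each library left out in turn. Without the first wild-type NarQ library 4 nitrogen-limitation, 8 amino acid and 4 general stress genes were called higher, without the first deletion empty-vector library 1, 1 and 0, and without the first deletion NarQ library 11, 9 and 6. The smallest adjusted p was 0.0261, and 104 loci lay at that value or under 0.03. Median-ratio scaling moved the median of all loci from 0.145 to 0.016 and left 130 calls, 70.8% of them higher against 80.2% before, and quantile normalization left 93, 64.5% higher. Under the former the list medians were 1.35 for nitrogen limitation, 0.84 for amino acid biosynthesis, 0.89 for general stress, -1.08 for ribosomal proteins and -0.82 for sulfate assimilation. Without a trend in its variance prior limma called 0, with 1045 loci at an unadjusted p under 0.05.

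Log2 fold changes with NarQ in wild type and in the deletion strain, which rest on different control libraries, correlated across the 4651 loci at Pearson r = 0.309 and Spearman rho = 0.200; loci are not independent replicates. Pearson r was 0.251 with a pseudocount of 0.1. Among loci called in both, 15 rose in both strains where independent lists would share 3.81, and 86 fell in both where 13.1 would be shared, while 12 were called in opposite directions. Both comparisons used the same variance estimate of each locus, so their calls were not independent and these expected numbers may be too low. No expected number was computed for the opposite calls. narQ, the 4 pga genes and acrD, a drug efflux pump gene (1.27 and 1.14), rose in both. Of the loci called in opposite directions, glpQ alone rose in wild type (1.05) and fell in the deletion strain (-0.79). All the others fell in wild type and rose in the deletion strain, among them glnK (-1.66 and 2.30), nac (-1.27 and 1.56) and amtB (-1.19 and 1.52). acrD has the locus tag that follows that of narQ and was singled out, like glpQ here, after its values were seen.

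**Figure D3:**
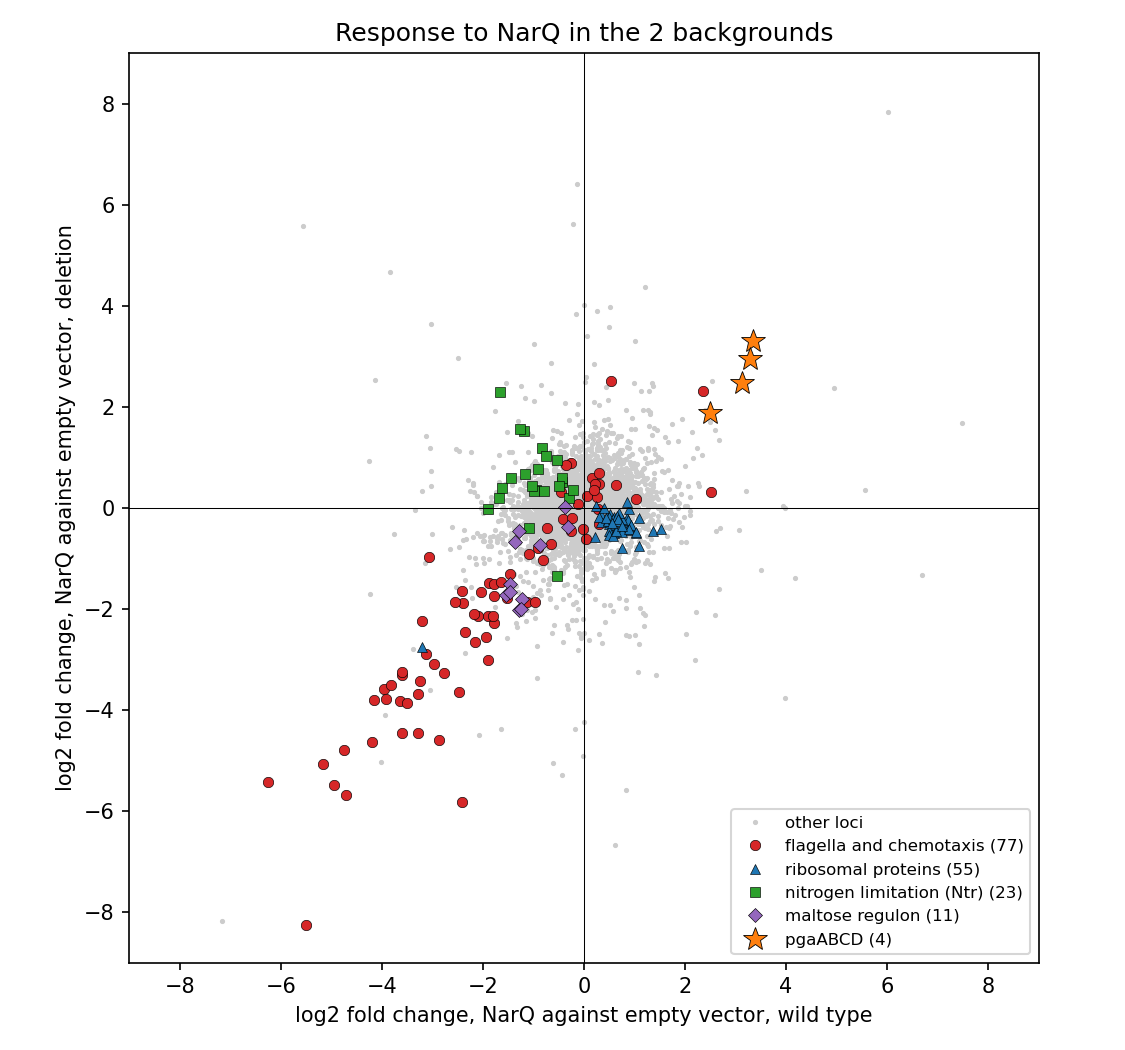
Log2 fold change of log2(FPKM + 1) with NarQ in wild type (x axis) against that in the deletion strain (y axis) for 4649 loci, each a point, with 2 loci beyond the axes. Coloured points mark 77 flagellar and chemotaxis, 55 ribosomal protein, 23 nitrogen-limitation and 11 maltose loci and the 4 pga genes; the flagellar medians were -1.87 and -1.86.

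The third line of comparison set the deletion strain against wild type, both with empty vector. Acid resistance genes were higher: hdeA, a periplasmic acid chaperone, stood at 10140 ± 2510 against 2334 ± 410 FPKM (2.11 ± 0.25, adjusted p = 0.017), hdeB at 1.84 and the activator gadE at 2.14, and 9 of 13 measured members rose, 0 fell and 4 were not called, 9 adjusted over the list alone. For acid resistance genes camera gave adjusted p = 5.64e-08, and adjusted p = 0.121 with an estimated correlation. Iron uptake genes rose in 6 of 26 cases and fell in 0 (10 rose adjusted over the list alone), with the ferrous iron transporter genes feoA at 2.07 and feoB at 1.66 and the enterobactin esterase fes at 1.42. For iron uptake genes camera gave adjusted p = 1.27e-05, and adjusted p = 0.239 with an estimated correlation. The sulfate-binding protein gene sbp fell from 231 ± 59.6 to 22.2 ± 4.46 FPKM (-3.31 ± 0.24, adjusted p = 0.00527), cysP was at -1.36 and cysK at -0.98, and 7 of 21 sulfate genes fell and 0 rose (12 fell adjusted over the list alone). For sulfate assimilation genes camera gave adjusted p = 5.28e-06, and adjusted p = 0.239 with an estimated correlation. Nitrate-induced genes fell in 7 of 29 cases and rose in 0 (9 fell adjusted over the list alone), among them napA (88.9 ± 17.1 to 10.3 ± 1.7 FPKM, -2.99, adjusted p = 0.00593), napH (-2.70), napF (-2.49) and narH (ECW_RS06770; -1.40), and napD was 21.9 and 53.1 FPKM in wild type and listed at 0 in both deletion libraries. For nitrate-induced genes camera gave adjusted p = 0.00262, and adjusted p = 0.239 with an estimated correlation. The nitrate-repressed genes frdA (1.16) and focA (0.69) were the 2 of 21 that rose, 0 fell, and 3 rose adjusted over the list alone. For nitrate-repressed genes camera gave adjusted p = 0.00982, and adjusted p = 0.242 with an estimated correlation. metF, of methionine synthesis, rose by 2.32. Ribosomal protein genes fell in 7 of 55 cases and rose in 0 (35 fell adjusted over the list alone), with rpsE at -1.01 and rplO at -1.18. For ribosomal protein genes camera gave adjusted p = 5.49e-12, and adjusted p = 0.363 with an estimated correlation. Nitrogen-limitation genes fell in 6 of 23 and rose in 0 (12 fell adjusted over the list alone), with glnQ at -1.10 and glnA at -0.75. For nitrogen-limitation genes camera gave adjusted p = 5.07e-08, and adjusted p = 0.239 with an estimated correlation. The 12 housekeeping reference genes had a median of -0.27, 1 fell, 0 rose, and 4 fell and 1 rose adjusted over the list alone. For the housekeeping genes camera gave adjusted p = 0.0262, and adjusted p = 0.436 with an estimated correlation.

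Of 21 carboxylate transporters garP (1.12) and focA (0.69) rose, kgtP fell from 204 ± 31.3 to 90.1 ± 11 FPKM (-1.17, adjusted p = 0.0318) and 18 were not called, and 3 rose and 3 fell adjusted over the list alone. Their median was -0.10 and their mean -0.001 while camera gave the direction up, and the list was not called (adjusted p = 0.965; adjusted p = 0.969 with an estimated correlation). In the propionate and 3-HP list 0 of 10 were called by limma and 2 fell adjusted over the list alone, with acs at -0.65 (adjusted p = 0.0611) and the aldehyde reductase yqhD at -0.79 (adjusted p = 0.0862; camera 0.109, adjusted p = 0.294 with an estimated correlation). In all 275 loci were called, 122 higher and 153 lower, 123 of them with an absolute log2 fold change of at least 1, and 20 of the 32 lists, 5 up and 15 down, 0 with an estimated correlation. The calls fell to 5 and 7 without the first and the second wild-type empty-vector library and to 29 and 1 without the first and the second deletion empty-vector library; without either wild-type NarQ library they numbered 171 and 170, and 82 without a trend in the variance prior. Of 40 named genes called, 1 (narX) kept its call with each library left out in turn. narX is among the genes deleted in this strain. The list of the nar regulator genes (median -4.09) was among those called down, and both calls followed from the design. For acid resistance 0, 0, 3 and 0 genes were called without those 4 empty-vector libraries in that order, for iron uptake 0, 1, 1 and 0, for sulfate 1, 1, 1 and 0, for nitrate-induced genes 0, 0, 2 and 0. For nitrate-repressed, ribosomal, nitrogen-limitation and carboxylate genes the count was 0 each time, where limma gave 650, 670, 1110 and 858 loci an unadjusted p under 0.05. Without either wild-type NarQ library 3 nitrate-induced, 1 nitrate-repressed and 2 nitrogen-limitation genes were called, and without either deletion NarQ library 3 nitrogen-limitation genes.

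The last comparison set the deletion strain against wild type, both with NarQ. Ribosomal protein genes fell in 52 of 55 cases, 0 rose and 3 were not called, and 53 fell adjusted over the list alone. rpsC stood at 1629 ± 235 against 6596 ± 1220 FPKM (-2.01 ± 0.18, adjusted p = 0.00144), rplV at -2.34, rplD at -1.87 and rpsE at -1.79. For ribosomal protein genes camera gave adjusted p = 2.35e-28, and adjusted p = 0.294 with an estimated correlation. Sulfate assimilation genes fell in 15 of 21 cases, 1 (ssuB) rose and 5 were not called, likewise adjusted over the list alone: sbp was 361 ± 6.58 FPKM in wild type and 21.8 ± 4.57 in the deletion strain (-4.00 ± 0.24, adjusted p = 0.000767), cysC was at -2.08 and cysJ at -2.02. For sulfate assimilation genes camera gave adjusted p = 1.33e-08, and adjusted p = 0.238 with an estimated correlation. Acid resistance genes rose in 8 of 13 cases and fell in 0 (9 rose adjusted over the list alone), with hdeA at 3.03, hdeB at 2.90 and the glutamate antiporter gadC at 2.23. For acid resistance genes camera gave adjusted p = 0.000142, and adjusted p = 0.238 with an estimated correlation. Iron uptake genes rose in 14 of 26 cases and fell in 0, likewise adjusted over the list alone, with feoA at 3.01 and the ferrichrome receptor fhuA at 1.46. For iron uptake genes camera gave adjusted p = 0.000211, and adjusted p = 0.291 with an estimated correlation. General stress genes rose in 11 of 18 cases and fell in 0 (12 rose adjusted over the list alone), with wrbA at 1.86 and cbpA at 1.77. For general stress genes camera gave adjusted p = 1.71e-05, and adjusted p = 0.291 with an estimated correlation. Single genes outside these lists included uhpT (3.66) and the outer membrane protein gene ompW (16.0 ± 9.72 to 133 ± 13.8 FPKM, 3.10, adjusted p = 0.00267). In all 1328 loci were called, 884 higher and 444 lower, 588 of them with an absolute log2 fold change of at least 1. Of these calls 66.6% were higher, against 54.9% after median-ratio scaling, which moved the median of all loci from 0.068 to -0.038, and 54.8% after quantile normalization. The count was 642 and 829 without the first and the second wild-type NarQ library, 752 without the second deletion NarQ library and 588 with the NarQ libraries alone, and 46 of 56 named genes called kept their call with each library left out in turn. The iron uptake count was 8 and 9 without the first and the second wild-type NarQ library; ssuB was not called without either of them, either wild-type empty-vector library or either deletion NarQ library.

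Nitrogen-limitation genes rose in 16 of 23 cases and fell in 0, likewise adjusted over the list alone, with nac at 1.88 and glnG at 1.56. For nitrogen-limitation genes camera gave adjusted p = 0.000322, and adjusted p = 0.316 with an estimated correlation. Amino acid biosynthesis genes rose in 22 of 43 cases and 1, cysteine synthase cysK (-1.16), fell, likewise adjusted over the list alone, with lysA at 2.05 and ilvC at 1.91. For amino acid biosynthesis camera gave adjusted p = 6.06e-05, and adjusted p = 0.261 with an estimated correlation. Fermentation genes rose in 9 of 24 cases and fell in 0 (9 rose and 1 fell adjusted over the list alone): frdA was 31.0 ± 1.95 FPKM in wild type and 235 ± 31.3 in the deletion strain (2.88 ± 0.17, adjusted p = 0.000767), frdD was at 2.17 and adhE at 0.98. For fermentation genes camera gave adjusted p = 0.0077, and adjusted p = 0.28 with an estimated correlation. Of 29 nitrate-induced genes 5 fell, 1 rose and 23 were not called, likewise adjusted over the list alone: narJ (-3.33), the nitrate transporter narK (-2.91), narH (ECW_RS06770; 87.8 ± 18.1 to 11.6 ± 0.667 FPKM, -2.81), narI (ECW_RS06780; -2.57) and fdnG (ECW_RS08210; -1.90) fell, and a second locus carrying the symbol fdnG (ECW_RS21500), named after its values were seen, rose by 0.57. Whether that second locus is a nitrate-induced gene could not be read from its symbol. The median of the nitrate-induced list was 0.008 (-0.093 after median-ratio scaling) and its mean -0.42, and camera, which gave the direction down, did not call it (adjusted p = 0.346; adjusted p = 0.562 with an estimated correlation). Nitrate-repressed genes rose in 8 of 21 cases and fell in 0 (9 rose adjusted over the list alone). Their list was not called (camera adjusted p = 0.0627, and adjusted p = 0.303 with an estimated correlation). Of 21 carboxylate transporters the acetate and succinate carrier satP (-0.76), putP, a proline symporter (-0.66), and dcuA (-0.46) fell, focA rose by 0.61 and 17 were not called, likewise adjusted over the list alone (camera adjusted p = 0.203; adjusted p = 0.425 with an estimated correlation). In the propionate and 3-HP list prpR (31.1 ± 1.11 to 57.4 ± 4.88 FPKM, 0.86, adjusted p = 0.0126) and ydfG (0.54, adjusted p = 0.0213) rose, 0 fell and 8 were not called, likewise adjusted over the list alone (camera adjusted p = 0.479; adjusted p = 0.628 with an estimated correlation). The nitrogen-limitation count was 8 without the first or the second wild-type NarQ library or the first deletion NarQ library and 10 without the second deletion or either wild-type empty-vector library. The fermentation count was 6 without the second wild-type NarQ library. focA and ydfG were not called without either wild-type NarQ library or the second deletion NarQ library, satP and dcuA also not without either wild-type empty-vector library, putP not without the second NarQ library of either strain, and prpR not without the first wild-type NarQ library. The ECW_RS21500 call was lost without the first wild-type or the second deletion NarQ library. Of the 32 lists 11 were called, 6 up and 5 down, and 0 with an estimated correlation. Among those down was the list of the nar regulator genes (median -3.98), a call that followed from the deletion.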

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

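Of the tests weighed in this part, the one on length bias was set out before its result was seen, and the other 8 tests were chosen only after the result was seen.

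A difference of the NarQ effect between the strains, by the interaction test of limma, marked 50 genes and 9 lists. The 50 were those, among all 217 interaction calls, that were named in any comparison or list or singled out after their values were seen. Loci with a group at 0 throughout were left out. Each of the gene calls is lost when single libraries are left out. Among nitrogen-limitation and arginine genes the differences were 3.964 for glnK, 2.827 for nac, 2.707 for amtB, 2.031 for glnG, 1.880 for astB, 1.873 for astD, 1.838 for glnQ, 1.778 for astC, 1.482 for glnA, 1.289 for glnP and 1.115 for hisJ. For respiration and fermentation genes they were 3.540 for napB, 3.295 for napA, 1.241 for napC, 2.232 for frdD, 1.718 for frdA, -2.242 for fdnG (ECW_RS08210) and -2.592 for ECW_RS06765, a nitrate reductase alpha subunit. For transport genes they were 3.455 for uhpT, 1.423 for kgtP, -1.089 for glpT, -1.418 for cysW, -1.520 for mglC and -1.950 for zinT. For amino acid and sulfur metabolism they were 3.326 for lysA, 2.689 for trpB, 2.572 for trpA, 1.426 for hisH, -1.581 for metF and -1.188 for cysI, and -1.836 for glpQ. For cellulose and stress genes they were 2.616 for bcsF, 1.570 for bcsB, 1.152 for bcsG, 1.642 for yeaG, 1.534 for wrbA, 1.429 for cbpA, 1.425 for katE, 1.358 for otsB, 1.143 for gadC, 1.125 for poxB, 0.891 for slp and -1.249 for ydfK. The rest were 1.806 for narQ, -1.943 for rpsO, -1.808 for rpsT, -1.531 for rplV, -1.658 for wzy, -1.821 for ECW_RS11280 and -1.868 for ECW_RS10025. The value of narQ followed from the design and is no response to NarQ. With the plasmid narQ stood at 1880 FPKM in wild type and 1697 in the deletion strain. With empty vector it stood at 27.9 and 6.48 FPKM, since the deletion strain lacks the gene by its label. The medians of the lists, none of which was called with an estimated correlation, were 1.482 for nitrogen limitation (adjusted p = 0.399 with an estimated correlation), 1.076 for arginine and tryptophan catabolism (camera adjusted p = 0.000403, adjusted p = 0.399 with an estimated correlation), 1.023 for general stress (adjusted p = 0.402 with an estimated correlation), 0.975 for amino acid biosynthesis (adjusted p = 0.399 with an estimated correlation), 0.711 for oxidative stress (adjusted p = 0.00261, adjusted p = 0.446 with an estimated correlation), 0.460 for heat shock (adjusted p = 0.0454, adjusted p = 0.576 with an estimated correlation), 0.415 for envelope stress (adjusted p = 0.0329, adjusted p = 0.446 with an estimated correlation), -0.684 for sulfate assimilation (adjusted p = 0.399 with an estimated correlation) and -0.945 for ribosomal proteins (adjusted p = 0.446 with an estimated correlation).

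Flagellar genes were lower with NarQ in both strains. Scaling between libraries was excluded, since the list median nearest 0 over both scalings and strains was -1.752. Reads moving to the second flagellar gene set were excluded too: those 25 loci had medians of 0.166 and 0.225, and none had a mean above 15.7 FPKM. A lower transcript of the master regulator genes flhD and flhC could neither be shown nor excluded, with a largest fall of -0.718 for flhC in the deletion strain (limma adjusted p = 0.106). How NarQ might act on motility was not tested.

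Ribosomal protein genes were lower in the deletion strain than in wild type with NarQ. For each of 53 ribosomal genes the median change of other abundant loci of matched length was taken. The median of these medians was -0.079, and the quartiles over all 460 matched loci were -0.387 and 0.473. Length bias of short genes was therefore excluded. Scaling as the only source was excluded by a list median of -1.069 or lower under both scalings. The median was -1.685 in the values as deposited, so the size of the difference depended in part on the scaling. A single library was excluded by 40 or more of 55 members called lower with each library left out. A difference in growth rate or growth stage at harvest could give this pattern and was not tested.

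acrD, whose locus tag follows that of narQ, rose from 22.5 ± 0.497 to 55.7 ± 5.13 FPKM in wild type and from 23.8 ± 6.72 to 52.6 ± 2.66 in the deletion strain (n = 2 each). Its gain was 1.79% (SE 0.210) and 1.70% (SE 0.306) of the gain of narQ, a difference of -0.093 (SE 0.371), as reads of the plasmid narQ transcript counted in acrD would give; a regulated rise of equal size could give this too. Scaling was excluded by a smallest rise of 1.064 (largest adjusted p = 0.0409). The other BaeR-activated genes mdtA, mdtB, mdtC and spy rose by at most 0.343 in either strain. Their highest upper bound, the estimate plus 2 SE, was 0.920. A rise of 1 or more shared with these genes was thus excluded, and a smaller shared rise was not.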

How the results depend on the processing

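None of the tests in this part were chosen only after the result was seen, apart from the list alternative without shared symbols. Over 249 pairs of named gene and comparison, 3439 values kept their direction and side of the threshold, 744 became weaker, 2 stronger and 11 reversed; list tests gave 151, 38 and 7 with 0 reversed. With both filters, a pseudocount of 10, the replicate block and lists without shared symbols the total of calls and of called lists in each comparison stayed within 1.5 times of its value. With the replicate block, the calls numbered 732, 136, 152, 254 and 1264 in the order of the comparisons. The higher calls for NarQ in the deletion strain were then 50 against 76. Replicate numbers were not used as pairs, since the labels do not say that equal numbers share a culture or day. Deviations of equal replicate numbers correlated between groups at -0.020 to 0.232. The highest value was that of the deletion strain with empty vector and with NarQ, so a shared effect there was not excluded. Unknown depth limits what can be said of low genes.

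With each library left out in turn, calls ranged from 114 to 821 for NarQ in wild type, from 41 to 274 for NarQ in the deletion strain, from 0 to 229 for the interaction, from 1 to 224 for the strains with empty vector and from 642 to 1338 for the strains with NarQ, and the correlation of the NarQ effects from 0.211 to 0.332 (0.251 with a pseudocount of 0.1). With only the libraries of the groups compared, fewer libraries estimate the variance. There were then 20 calls for NarQ in the deletion strain, 195 for the strains with empty vector and 588 for the strains with NarQ. For NarQ in wild type the calls rose from 771 to 864. These fits change both the number of libraries and the spread that the groups share, so the counts cannot tell these apart. The interaction gave 130 calls with median-ratio scaling, 93 with quantile normalization and 0 by limma without trend (1045 at an unadjusted p under 0.05), and the strains with empty vector gave 82 without trend. Lists called with an estimated correlation numbered 0, 1, 0, 0 and 0 in the order of the comparisons, and those called by fry 23, 13, 13, 19 and 19. The cause of the moved values was not tested.

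Values that reversed, none past the threshold, were under quantile normalization narX (0.026) and narP (0.000) for NarQ in wild type, narP for NarQ in the deletion strain (0.057) and for the interaction (0.057), and narQ for the strains with NarQ (0.120), and with a pseudocount of 10 narP for the interaction (0.156). With a library left out, narP ranged from -0.985 to 0.541 for NarQ in the deletion strain and from -0.800 to 0.727 for the interaction (0.059 without the first wild-type empty-vector and 0.014 without the second wild-type NarQ library), and narL from -0.035 to 0.549 for the interaction. The cause was not tested.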

Other observations

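The genes in this part were chosen after their values were seen, and no further tests were run on them. With NarQ in wild type the O-antigen polymerase gene wzy rose from 745 ± 76 to 2234 ± 264 FPKM (n = 2 each; log2 fold change 1.58, limma adjusted p = 0.00697), the flippase gene wzx rose by 1.52 (adjusted p = 0.0144), and the glycosyltransferase loci ECW_RS11270, ECW_RS11280, ECW_RS11285 and ECW_RS11290 by 1.65, 1.72, 1.75 and 1.89. In the deletion strain these 6 lay between -0.10 and 0.10, and none was called; the interaction was called for wzy and ECW_RS11280 alone. Of the cellulose genes, bcsF fell in wild type by a log2 fold change of -1.80 (adjusted p = 0.0117), bcsB by -1.12, bcsC by -0.87 and bcsG by -0.63, while bcsA, bcsE and bcsQ were not called. Of the loci named as GGDEF-domain proteins or diguanylate cyclases, which were not tested as a list, ECW_RS05815 rose from 72.0 ± 12 to 465 ± 54.2 FPKM (2.68, adjusted p = 0.00367; 1.34 in the deletion strain, adjusted p = 0.0536) and ECW_RS10025 by 1.86 (adjusted p = 0.00581). dgcZ rose by 0.67 in wild type (adjusted p = 0.0495) and was also called in the deletion strain, with a rise of 0.905. In wild type dgcM changed by -0.84 (adjusted p = 0.0219), and 8 others were not called.

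Among cold shock genes, which were not tested as a list, cspG rose in wild type with NarQ from 27140 ± 2700 to 116400 ± 23100 FPKM (2.09, adjusted p = 0.00678; not called without either wild-type empty-vector library), ydfK by 1.31, cspF by 1.17 and cspI by 1.13, while cspB stood at 2.03 (adjusted p = 0.0598) and cspA at 1.11 (adjusted p = 0.191), and cspD, cspH and both cspE loci were not called. ECW_RS06765, a nitrate reductase alpha subunit without symbol, rose from 40.9 ± 7.61 to 157 ± 3.39 FPKM (1.92, adjusted p = 0.0061) and was lower in the deletion strain with empty vector (-2.41, adjusted p = 0.0153) and with NarQ (-5.01, adjusted p = 0.000767). ECW_RS27915, a hypothetical protein locus, was listed at 583600 and 52280 FPKM in the deletion libraries with empty vector and at 0 in the other 6.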
